A study of Mus musculus with 46 samples.

How the data were processed

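Mouse lung group 2 innate lymphoid cells (ILC2s) were studied in 46 libraries of 14 groups, made from live CD45+ CD90.2+ CD127+ cells without lineage markers, per the labels. Cultured cells had received IL-7 with or without IL-33 and with or without the neuropeptide CGRP for 6 hours or 3 days, and each of these 8 groups held 4 libraries for full-length RNA sequencing from 2 ng of RNA. The 4 libraries carried 2 batch letters with 2 numbers each. The 2 libraries of a batch were read as technical, summed and rounded before testing, so n was 2 per group. The series design text says that each biological replicate was split into 2 technical replicates. At 6 hours with IL-7 the log2 values of single libraries differed by a standard deviation of 1.007 and 1.436 within and 1.267 between batches. Mice had received PBS, CGRP, IL-33 or both by the nose for 3 days, and their sorted cells were read by droplet-based 3' single-cell RNA sequencing with 2 libraries per group. Chromatin accessibility (ATAC-seq) was measured after 6 hours in IL-7 and IL-33 with and without CGRP, with 3 libraries per group of 6000 cells.

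The bulk RNA values were estimated counts per gene that the authors had obtained before deposit with the pseudoaligner kallisto 0.42.3, per the submitters' processing notes. Estimated counts are not whole numbers and share reads between similar genes by a model, so genes with close relatives, such as Calca with Calcb, carry extra uncertainty. The deposited table held 20572 genes, of which 4178 were zero in every library, and library totals lay between 13.4 and 21.8 M with 9851 to 13510 genes detected. The single-cell values were molecule (UMI) counts per cell and gene for 27998 features, which the authors had made with Cell Ranger 1.3 before deposit, per the submitters' processing notes. The deposited ATAC values were a normalized signal for 92814 regions, with coordinates on mm10, and by their values the authors had added 1 to each read count and divided by 1 size factor per library. Bowtie2, MACS2, bedtools and DESeq2 stand in the submitters' processing notes for this, without a word on which step each of them did.

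The design had been written before the data were examined and assumed raw read counts for ATAC. The deposited values with sample names were a normalized signal, so limma 3.58.1 on the log2 signal, with a trend and robust variances, became the test for regions. Dividing each library by 1 factor gave whole numbers for every value within 0.01, and these recovered reads served for the low-count filter and for alternatives. Recovered reads in regions were 7.22, 7.15 and 6.78 M without CGRP and 9.12, 8.92 and 10.77 M with CGRP. The labels wt and cgrp of the table were read as IL-7+IL-33 and IL-7+IL-33+CGRP, the only groups with ATAC libraries. The nearest protein-coding gene span within 100 kb in the GRCm38.p6 reference was given to each region, because the reference at hand had no strand from which to place a transcription start.

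Bulk genes and summed single-cell counts were tested with edgeR 4.0.16 in R 4.3.3. The low-count filter of edgeR, TMM factors and robust quasi-likelihood fits were used, with 1 coefficient per group, a batch term, and the Benjamini-Hochberg adjustment across genes of each comparison. A gene or region was called at an adjusted p below 0.05. In each of the 3 experiments 4 comparisons were made, which gave 12 for genes besides 1 for regions. They were IL-33 against none, CGRP against none without IL-33, CGRP against none with IL-33, and the difference between both CGRP effects. The batch term rested on the batch letters of the labels, and deviations of paired samples from their group means correlated at 0.014 to 0.064 at 6 hours, 0.034 to 0.082 at 3 days and 0.226 to 0.506 in vivo. With 2 samples against 2, no exact rank test could give a p below 0.333, so all evidence per gene rests on the model's sharing of variance between genes. Gene lists, 25 of them with 462 genes fixed in advance, were tested with camera of limma on voom weights with a preset correlation between genes of 0.01, and again with the correlation estimated from the data.

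Single cells were kept with at least 500 genes and at most 15% mitochondrial UMIs, which left 33437 of 36245 barcodes. Scanpy 1.11.5 under Python 3.11.15 scaled cells to 10000 UMIs, took 2000 variable genes, 30 principal components and 15 neighbours, and clustered with Leiden (leidenalg 0.10.2) at resolution 1.0. Of 17 clusters, 9 were named ILC2-like by marker lists that held genes also reported as results, such as Il13, Il5 and Klrg1. The same 9 were named when the 34 fixed genes were left out of the lists. Their 22949 cells, 2207 to 3841 per library, were summed per library. Clusters 2, 10, 11 and 16 scored best for ILC2 markers but stayed out unnamed, cluster 11 for its low UMI number and the other 3 for a marker of another cell type among their top genes. Cluster 2 held 20.8% of cells with PBS, 24.0% with CGRP, 1.00% with IL-33 and 14.2% with IL-33+CGRP, and cluster 10 held 0.879%, 0.470%, 9.59% and 1.11%. Scrublet called at most 0.052% of a library doublets, far too few to be useful, so doublets were not removed; leaving out the 5% of cells with the most UMIs served as an alternative. Shares of cells with a UMI were also taken after thinning every cell to 2000 UMIs.

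Genes named below came from rules set in advance: 34 fixed genes, the 10 largest called changes per direction among genes at 10.0 counts per M (CPM) or more in a group of the comparison, 5 per direction for the difference, and up to 4 members of each called list. The largest changes were taken only from genes with the same direction in both batches. Among all genes that these rules gave, those whose call held when any 1 sample was left out were preferred for the text, a choice made after the results were seen. The share of named results that stayed past the threshold under every alternative was 103 of 155 at 6 hours, 0 of 41 at 3 days, 91 of 130.0 in vivo and 16 of 37 for regions. Where a gene had no count in a group, the fold is given as a lower bound with 3 counts over that group as the floor. An error after ± is the standard error of a log2 fold change, or the standard deviation between samples where said.

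The comparison of CGRP with IL-33 in each experiment was simulated with the depth and spread of the real samples and 200 changed genes or regions, and no other comparison with changes was. At 6 hours 14.5% of 1.5-fold, 52.4% of 2-fold and 90.7% of 4-fold changes were recovered, and 4.7% of calls were false. At 3 days the recovery was 0%, 1.2% and 22.2%, in vivo 82.8%, 98.6% and 98.5% with 10.1% false calls, and for regions 18.2%, 47.7% and 88.4%. No gene was called in a simulated comparison without change, and 0 of 20 random sets of unchanged genes were called in each simulated RNA experiment. Genes were drawn independently, so the random sets do not show how the preset correlation deals with genes that vary together.

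Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, a 10.0 CPM filter, no batch term, an estimated absolute log2 fold change of at least 1 required of a call, each library as its own sample, only the first library of each batch, both times in 1 fit, each sample left out in turn, all cells in place of ILC2-like cells, and sums or libraries thinned to the smallest. For regions, DESeq2 was run on recovered reads, and edgeR on them was added after the signal had been recognised. The unnormalized ATAC table was left out because its columns had no sample names. Il4 in culture, with 22 and 23 counts in all, and Il9 in vivo, with 40 counts, were not tested because the low-count filter removed them.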

Results

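Gene expression was measured in mouse lung ILC2s, innate lymphocytes that release type 2 cytokines, after exposure to the alarm cytokine IL-33, the neuropeptide CGRP, or both. Cultured ILC2s were held in IL-7 alone or with CGRP, IL-33 or both added, for 6 hours or 3 days, with 2 samples per group after the technical libraries had been summed. Mice received PBS, either agent or both, with 2 single-cell libraries per group. Chromatin accessibility was measured in 3 libraries per group after 6 hours in IL-7+IL-33 and in IL-7+IL-33+CGRP.

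Totals of estimated counts at 6 hours were 37.0 and 36.6 M with IL-7, 34.5 and 33.7 M with IL-7+CGRP, 39.9 and 38.1 M with IL-7+IL-33, and 30.3 and 28.3 M with all 3. At 3 days they were 30.3 and 32.2, 33.4 and 28.7, 36.7 and 33.7, and 34.8 and 35.8 M in the same order. The summed UMIs of ILC2-like cells were 13.5 and 14.3 M with PBS, 12.7 and 15.2 M with CGRP, 39.7 and 40.8 M with IL-33, and 27.8 and 21.5 M with IL-33+CGRP. ATAC reads in regions were 6.78 to 7.22 M without CGRP and 8.92 to 10.77 M with CGRP. Levels are given as CPM ± standard deviation between 2 samples, and log2 fold changes ± standard error of the edgeR fit with n = 2 per group.

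The first question was what IL-33 does to cultured ILC2s within 6 hours. Il5, which encodes the eosinophil growth factor IL-5, rose from 157 ± 15 to 5368 ± 174 CPM, a log2 fold change of 5.10 ± 0.06. Il13, the cytokine behind mucus and airway reactivity, rose from 0.462 ± 0.214 to 165 ± 20.2 CPM (8.45 ± 0.40). Areg, an epidermal growth factor receptor ligand, rose from 4.11 ± 0.718 to 116 ± 18.3 CPM (4.81 ± 0.25). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 1.4e-07 for Il5, 2.1e-04 for Il13 and 1.1e-04 for Areg, and 1806 of 13279 genes were called, 1122 higher and 684 lower. Batch directions of called genes, here and below, come from the samples that made the calls and are no separate evidence. All 1806 moved the same way in both batches, and with 1 sample left out the number ran from 505 (without the second IL-7+IL-33 sample) to 871 (without the first IL-7 sample).

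Il9 had no count with IL-7 alone and 310 ± 156 CPM with IL-33, an increase of at least 8210-fold. Nr4a1, an immediate-early nuclear receptor, rose by 5.59 ± 0.14, and the chemokine gene Ccl1 by 5.79 ± 0.33. Dgat2, which completes triglyceride synthesis, rose by 7.06 ± 0.85 from 11.7 to 1379 CPM. Of the 22 measured NF-kB target genes 19 rose and 0 fell, and 21 rose when the adjustment ran over the list alone. Among them were Icam1 at 3.45 ± 0.15, the feedback inhibitor Nfkbia at 2.63 ± 0.08 and Tnfaip3 at 1.93 ± 0.08. For this list camera gave an adjusted p of 1.1e-17 with the preset correlation and 0.057 with the estimated one. Junb, which is not on that list, rose by 2.41 ± 0.13.

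Genes of MYC and ribosome biogenesis rose in 21 of 23 cases, with 23 over the list alone, among them Mybbp1a at 2.19 ± 0.11, Nolc1 at 1.81 ± 0.10, Nop56 at 1.77 ± 0.10 and the nucleolar Ncl at 1.51 ± 0.07. Myc itself rose by 1.66 ± 0.15. That list had a median of 1.71 and a camera adjusted p of 2.9e-25, or 0.062 with the estimated correlation. Of 20 cholesterol synthesis genes 12 rose (15 over the list alone), with Idi1 at 2.86 ± 0.12, Insig1 at 1.89 ± 0.14, Cyp51 at 1.87 ± 0.10 and Ldlr at 1.63 ± 0.11. The interleukin-2 receptor chain Il2ra rose by 2.07 ± 0.08, the kinase gene Pim2 by 3.10 ± 0.28 and the skin and lung homing receptor Ccr4 by 3.16 ± 0.10. The survival gene Bcl2 fell by 1.19 ± 0.16, the glucocorticoid-induced Tsc22d3 by 1.81 ± 0.15, the IL-25 receptor gene Il17rb by 1.18 ± 0.14 and the inhibitory receptor Cd200r1 by 1.16 ± 0.10. Ramp3, of the same gene family as the CGRP co-receptor gene Ramp1, fell by 1.86 ± 0.18, from 64.7 to 17.9 CPM. Summed markers of other cells moved too, those of mast cells and basophils from 22.2 and 20.5 CPM to 45.3 and 40.4 CPM, of T cells from 207 and 193 CPM to 128 and 107 CPM, erythroid ones from 22.2 and 19.7 CPM to 14.6 and 12.4 CPM, and those of ILC3s from 2990.0 and 2857 CPM to 2213 and 2225 CPM. The mast cell and basophil list, here and below, includes Cyp11a1, which is also reported below as a gene of these cultures, so its sum need not mark those cells. The ILC3 list likewise includes Lta, Ltb, Kit and Tmem176b, which are reported below as changed genes, so its sum need not mark ILC3s.

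**Figure D1:**
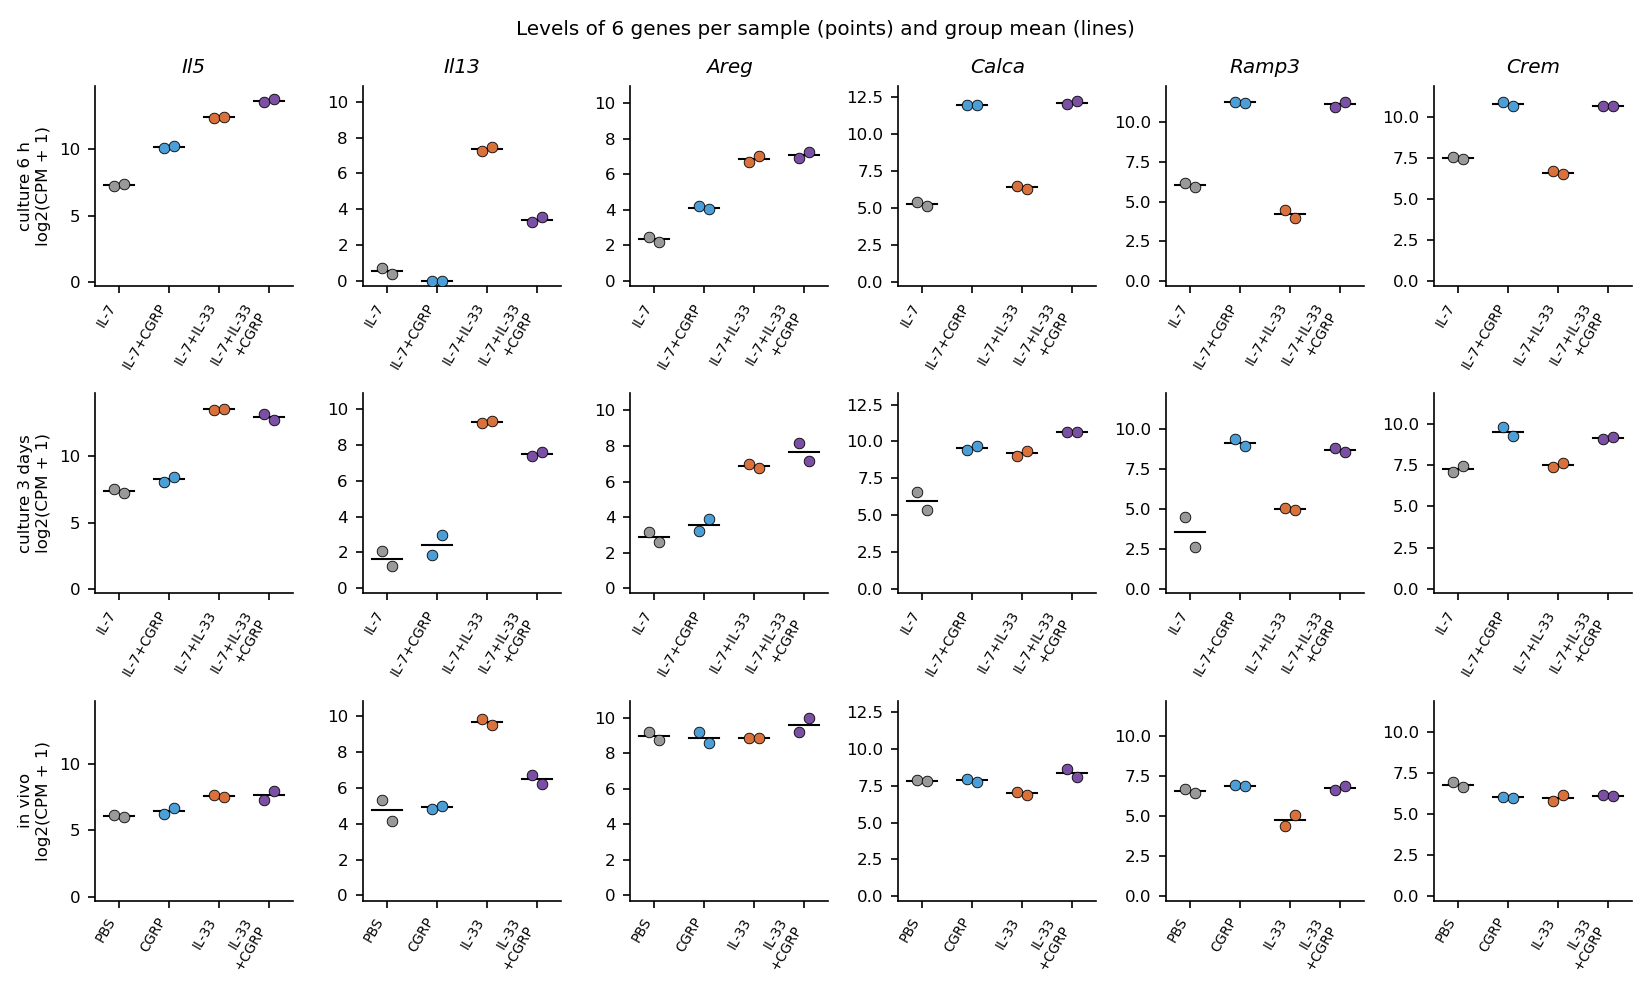
Levels of Il5, Il13, Areg, Calca, Ramp3 and Crem as log2 of CPM plus 1 on the vertical axis, by treatment on the horizontal axis, for culture at 6 hours, culture at 3 days and in vivo; points are samples (n = 2 per group) and lines are group means. Il13 with IL-33 stood at 165 CPM without and 9.73 CPM with CGRP at 6 hours, while Il5 stood at 5368 and 12660 CPM.

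CGRP without IL-33 at 6 hours showed what the neuropeptide does by itself. Calca, which encodes CGRP, rose from 37.3 ± 5.38 to 4012 ± 39.7 CPM, a log2 fold change of 6.75 ± 0.16. Ramp3 rose from 64.7 ± 6.87 to 2367 ± 24.7 CPM (5.20 ± 0.20), and the cAMP-inducible repressor gene Crem from 181 ± 6.71 to 1776 ± 176 CPM (3.29 ± 0.08). Il5 rose by 2.89 ± 0.06 and Areg by 1.98 ± 0.23 without any IL-33, whereas Il13, at 0.462 CPM with IL-7 alone, had no count with CGRP, at least 10.7-fold lower. That call for Il13 was lost without the first and without the second IL-7+CGRP sample, where the fitted log2 values, which are no bounds, were -7.08 and -6.99. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1152 genes were called, 624 higher and 528 lower, with an adjusted p of 3.6e-06 for Calca, Crem and Il5 and 2.9e-05 for Ramp3. All 1152 moved the same way in both batches, and 428 (without the second IL-7+CGRP sample) to 765 (without the first) were called with 1 sample left out.

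Of 30 measured cAMP and CREB target genes 12 rose and 0 fell (15 rose over the list alone), with Fosl2 at 3.40 ± 0.13, Rgs2, a brake on G-protein signals, at 2.53 ± 0.17, Sik1 at 2.14 ± 0.16 and Pde4b, which degrades cAMP, at 1.37 ± 0.14. The median was 1.00, and the camera adjusted p was 1.7e-09, or 0.15 with the estimated correlation. Tnfrsf9 rose by 5.06 ± 0.13, Pdcd1 (PD-1) by 2.45 ± 0.09, Tigit by 2.84 ± 0.17 and Icos by 1.13 ± 0.08. The transglutaminase gene Tgm2 rose by 6.73 ± 0.58, Odc1, the first enzyme of polyamine synthesis, by 3.13 ± 0.15, and Tnfaip3 by 2.78 ± 0.08. Il7r rose by 1.04 ± 0.08, Il1rl1, the IL-33 receptor, by 0.91 ± 0.08 and Gata3, the lineage regulator, by 0.53 ± 0.05. Of 20 genes of the unfolded protein response 12 rose and 0 fell (13 rose and 1 fell over the list alone), including Hsp90b1 at 1.52 ± 0.07, Hspa5 at 1.50 ± 0.07 and Calr at 1.46 ± 0.09, with a median of 1.19 and a camera adjusted p of 7.0e-13, or 0.091 with the estimated correlation.

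MYC and ribosome biogenesis genes moved the other way than with IL-33, 15 of 23 lower and 1 higher (20 and 1 over the list alone), with Dkc1 at -1.70 ± 0.17 and Mybbp1a at -1.32 ± 0.11. The median was -0.98 and the camera adjusted p 3.5e-10, or 0.15 with the estimated correlation. The prostaglandin E2 receptor gene Ptger4 fell by 2.60 ± 0.12, Tph1, which starts serotonin synthesis, by 2.85 ± 0.18, Bcl2 by 1.53 ± 0.16 and Il2ra by 1.20 ± 0.08. Lymphotoxin genes fell, Lta by 2.23 ± 0.24 and Ltb by 1.80 ± 0.12, and Tnf fell by 2.11 ± 0.22. Ramp1, which encodes the CGRP co-receptor, fell by 0.93 ± 0.10 and Arg1 by 0.96 ± 0.10. Id2 fell by 1.16 ± 0.07 and Tmem176b by 1.06 ± 0.12, and the summed markers of ILC3s, a sister lineage, went from 2990 and 2857 CPM to 1909 and 1808 CPM. Summed epithelial, endothelial and stromal markers went from 260 and 249 CPM to 105 and 73.7 CPM, those of mast cells and basophils from 22.2 and 20.5 CPM to 57.7 and 102 CPM, and myeloid ones from 313 and 361 CPM to 424 and 487 CPM. Those of T cells fell from 207 and 193 CPM to 167 and 151 CPM and erythroid ones from 22.2 and 19.7 CPM to 7.74 and 7.57 CPM.

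The central question of the series was what CGRP does to ILC2s that IL-33 has activated. At 6 hours CGRP lowered Il13 from 165 ± 20.2 to 9.73 ± 1.50 CPM, a log2 fold change of -4.09 ± 0.31, and Il9 from 310 ± 156 to 15.4 ± 0.594 CPM (-4.24 ± 0.31). Il5 instead rose from 5368 ± 174 to 12660 ± 1435 CPM, an increase of 1.23 ± 0.05. Areg at 116 and 135 CPM was not called (0.22 ± 0.21). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 7.4e-04 for Il13, 0.0015 for Il9, 3.9e-05 for Il5 and 0.55 for Areg, and 986 genes were higher and 1132 lower, 2118 in all. Both batches showed the same direction for all 2118, and leaving out 1 sample gave 661 (the second IL-7+IL-33 sample) to 1237 (the first IL-7+IL-33+CGRP sample).

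Calca rose by 5.77 ± 0.15, Ramp3 by 6.94 ± 0.22, Crem by 4.07 ± 0.08, Rgs2 by 3.52 ± 0.18, Tnfrsf9 by 4.43 ± 0.12 and Pdcd1 by 3.15 ± 0.10. Tgm2 rose by 9.97 ± 0.73 and the kinase scaffold gene Akap12 by 8.17 ± 1.05. Of 30 cAMP and CREB target genes 12 rose and 1 fell (13 and 3 over the list alone), with a median of 1.04 and a camera adjusted p of 1.2e-05, or 0.18 with the estimated correlation. Il1rl1 rose by 1.12 ± 0.08, Il7r by 1.28 ± 0.08, Icos by 1.67 ± 0.08, Il17rb by 1.22 ± 0.14 and Gata3 by 0.54 ± 0.05. In the list of ILC2 identity and receptors 10 of 24 genes rose and 6 fell (12 and 7 over the list alone), with a camera adjusted p of 0.019, or 0.18 with the estimated correlation.

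MYC and ribosome biogenesis genes fell in 21 of 23 cases and 1 rose (22 and 1 over the list alone), with a median of -1.91 and a camera adjusted p of 1.9e-20, or 0.14 with the estimated correlation. Myc fell by 1.97 ± 0.15 from 488 to 123 CPM, Mybbp1a by 2.29 ± 0.11 and Ncl by 1.65 ± 0.07. Of 22 NF-kB target genes 8 fell and 3 rose (11 and 3 over the list alone). Icam1 fell by 1.46 ± 0.14 and Nfkbia by 1.06 ± 0.08, whereas Tnfaip3 rose by 1.33 ± 0.08 to 1033 CPM. The median of that list was -0.35 and the camera adjusted p 0.0075, or 0.18 with the estimated correlation. The stress gene Gadd45g fell by 4.55 ± 0.20, the cytokine inhibitor Socs3 by 2.70 ± 0.34, Pim2 by 2.83 ± 0.28, Il2ra by 1.49 ± 0.08, Ptger4 by 3.20 ± 0.12 and the glutathione transferase gene Gstm1 by 3.62 ± 0.35. The integrin gene Itga4 fell by 1.39 ± 0.16 and Arg1 by 1.39 ± 0.10. Of 20 type 2 and effector cytokine genes 3 rose and 6 fell, with a median of -0.99 and a camera adjusted p of 0.53. Summed ILC3 markers were 2213 and 2225 CPM without and 1954 and 1920 CPM with CGRP. Those of mast cells and basophils went from 45.3 and 40.4 CPM to 66.5 and 96.0 CPM, and myeloid ones from 312 and 321 CPM to 453 and 454 CPM. Erythroid markers fell from 14.6 and 12.4 CPM to 7.23 and 7.24 CPM, and epithelial, endothelial and stromal ones from 240.2 and 279.6 CPM to 220.3 and 174 CPM.

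At 6 hours the CGRP effects with and without IL-33 shared more called genes than chance gives, though fewer than were called in only 1 of them. Of the 986 genes that it raised with IL-33, 460 were also raised without IL-33, where 46.3 were due by chance, and 380 of the 1132 lowered genes were lowered in both, where 45.0 were due, with 9 genes called in opposite directions. The difference between both CGRP effects, which asks whether IL-33 changes the response to CGRP, called 66 of 13279 genes, 22 higher and 44 lower. The number depended on the method, with 668 genes by DESeq2, 331 with a 10.0 CPM filter and 327 with each library as its own sample. Il5 had the smallest p in edgeR and differed by -1.65 ± 0.07, as the rise was 2.89 without IL-33 and 1.23 with it. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0012. Ccr4 differed by -2.09 ± 0.13, and its call was lost without the first (-2.14) or the second IL-7+IL-33 sample (-2.03) and without the second IL-7+IL-33+CGRP sample (-2.08), whereas the call for Il5 held with each sample left out in turn. All 66 had the same direction in both batches, but with 1 sample left out only 1 (without the second IL-7+IL-33+CGRP sample) to 13 genes (without the second IL-7 sample) were called.

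**Figure D2:**
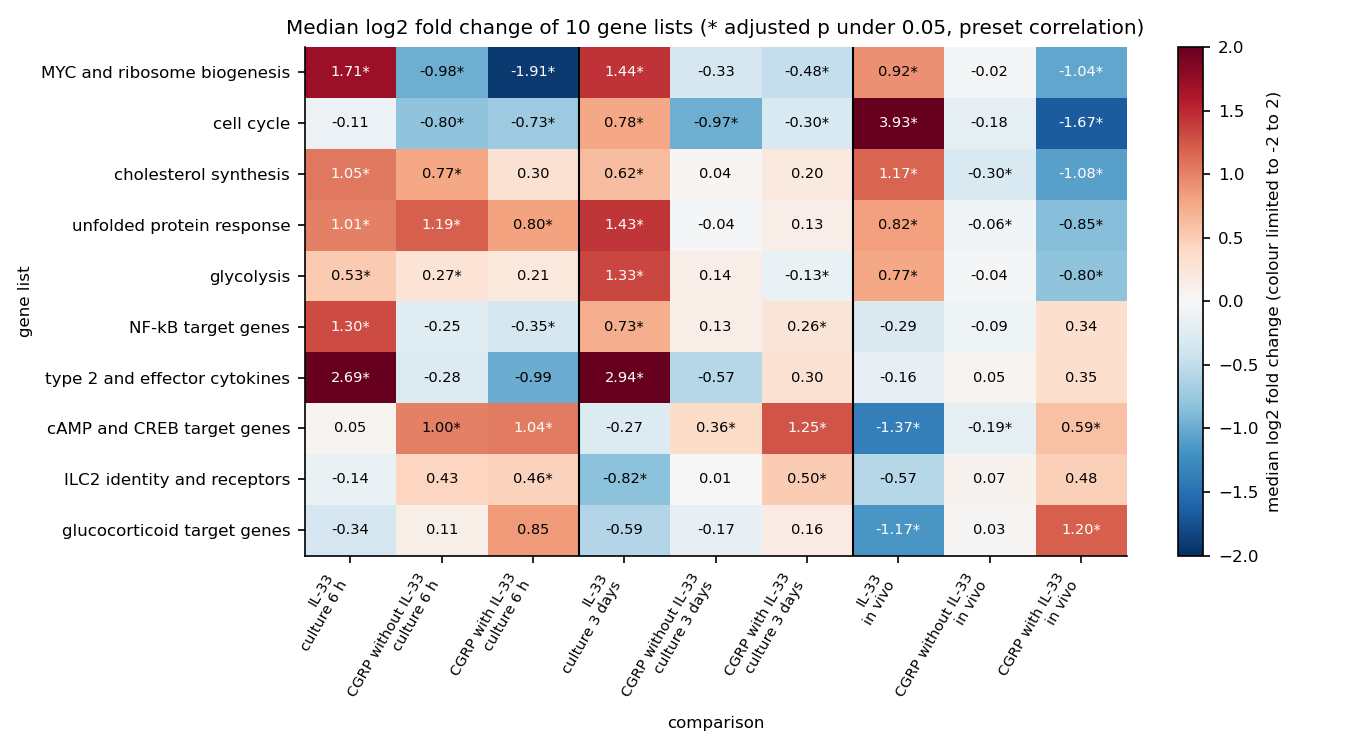
Median log2 fold change (colour, limited to -2 to 2) of 10 gene lists on the vertical axis in 9 comparisons on the horizontal axis, where a star marks a camera adjusted p below 0.05 with the preset correlation. With the estimated correlation camera called 0 of 300 list tests. The list of MYC and ribosome biogenesis stood at 1.71 with IL-33 and at -1.91 with CGRP added at 6 hours, and at 0.92 and -1.04 in vivo.

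After 3 days of culture, the question of the IL-33 effect was asked again for a longer exposure. Il5 stood at 169 ± 28.1 CPM with IL-7 and 11850 ± 489 CPM with IL-33, a log2 fold change of 6.14 ± 0.27. Il13 rose by 8.08 ± 0.71 to 624 ± 34.6 CPM and Areg by 4.22 ± 0.49 to 118 ± 14.0 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 690 of 13104 genes were called, 411 higher and 279 lower, with an adjusted p of 0.0029 for Il5, 0.010 for Il13 and 0.016 for Areg. All 690 moved the same way in both batches, yet with 1 sample left out only 0 (without the first IL-7 sample or either IL-7+IL-33 sample) to 6 genes (without the second IL-7 sample) were called. The calls for Il5 and Il13 were lost, with estimates of 6.33 and 9.12 without the first IL-7 sample, 5.96 and 7.38 without the second, 6.27 and 8.08 without the first IL-7+IL-33 sample, and 6.08 and 8.16 without the second. Such a fit takes the lone sample to vary like those of the other groups.

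Ldha, which turns pyruvate into lactate, rose by 1.70 ± 0.07 and Pgam1 by 2.16 ± 0.12. Of 18 glycolysis genes 10 rose and 0 fell (13 rose over the list alone), with a median of 1.33 and a camera adjusted p of 1.7e-12, or 0.16 with the estimated correlation. Calr rose by 1.71 ± 0.19, Manf by 1.85 ± 0.17, Hspa5 by 1.52 ± 0.13 and Nop56 by 1.44 ± 0.15. Cyp11a1, the first enzyme of steroid synthesis, rose by 4.23 ± 0.42 from 66.4 to 1185 CPM, Nr4a1 by 5.40 ± 0.62 and Calca by 3.18 ± 0.43. Il17rb fell by 4.44 ± 0.41, Ccr2 by 3.13 ± 0.10, Kit by 2.38 ± 0.15, Il7r by 2.06 ± 0.11, Il1rl1 by 0.99 ± 0.13 and Thy1 by 2.12 ± 0.29. Csf1 fell by 4.53 ± 0.49, the Notch ligand gene Jag1 by 5.16 ± 0.20, Bcl2 by 2.79 ± 0.27 and Gata3 by 0.83 ± 0.10. In the list of ILC2 identity and receptors 1 of 24 genes rose and 9 fell (2 and 13 over the list alone), with a camera adjusted p of 7.3e-07, or 0.24 with the estimated correlation. Summed mast cell and basophil markers went from 50.5 and 94.9 CPM to 1094 and 1102 CPM, and summed ILC3 markers from 2729 and 2496 CPM to 604 and 652 CPM. The mast cell and basophil list includes Cyp11a1. Its own 1185 CPM with IL-33, after TMM scaling, accounts for nearly all of that sum, so the rise is mostly that of a single gene. T cell markers went from 222 and 228 CPM to 69.3 and 74.8 CPM, myeloid ones from 483 and 1164 CPM to 279.5 and 385 CPM, B and plasma cell ones from 24.4 and 8.92 CPM to 49.5 and 47.0 CPM, and NK and ILC1 ones from 84.4 and 57.1 CPM to 20.2 and 48.1 CPM. Libraries with IL-7+IL-33 had 12748 to 13510 genes detected, against 11096 to 12481 with IL-7.

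CGRP at 3 days, asked without and with IL-33, called 0 of 13104 genes in each case and in their difference. edgeR counted 1565, 704 and 838 genes at an unadjusted p below 0.05, and DESeq2 with Benjamini-Hochberg adjustment called 994, 330 and 260. Without the batch term edgeR called 22 genes without and 9 with IL-33. Leaving out the first IL-7+CGRP sample gave 1312 calls without IL-33 and 557 for the difference. Only 22.2% of simulated 4-fold changes of CGRP with IL-33 were recovered at this depth and spread, so real changes could be missed. Without IL-33 the estimates were 5.58 ± 0.58 for Ramp3, 3.64 ± 0.34 for Pdcd1, 3.56 ± 0.44 for Calca, 2.30 ± 0.24 for Crem, -1.25 ± 0.14 for Arg1 and -1.34 ± 0.15 for the proliferation marker Mki67. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment their adjusted p lay at 0.093 for Ramp3 and Crem, 0.092 for Pdcd1, 0.11 for Calca, 0.099 for Arg1 and 0.095 for Mki67. With IL-33 the estimates were -1.81 ± 0.53 for Il13, at 624 and 179 CPM, -0.57 ± 0.22 for Il5, at 11850 and 8004 CPM, and 0.82 ± 0.43 for Areg. Arg1 stood at -2.24 ± 0.14, Icos at 1.09 ± 0.09, Il7r at 1.16 ± 0.11 and Ramp3 at 3.76 ± 0.53. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.64 for Il13, 0.88 for Il5, 0.071 for Arg1 and 0.072 for Icos and Il7r.

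Some lists were called at 3 days though none of their genes was. Without IL-33 the cell cycle list had a median of -0.97, with 21 of its genes lower over the list alone, and a camera adjusted p of 1.0e-12, or 0.23 with the estimated correlation. In that comparison erythroid markers went from 50.3 and 30.2 CPM to 5.51 and 16.2 CPM, myeloid ones from 483 and 1164 CPM to 639.6 and 1553 CPM, and mast cell and basophil ones from 50.5 and 94.9 CPM to 78.4 and 164 CPM. Libraries with IL-7+CGRP had 9851 to 11760 genes detected, against 11096 to 12481 with IL-7. With IL-33 markers of other cells also moved when CGRP was added, where summed ILC3 markers went from 604 and 652 CPM to 1375 and 1258 CPM, NK and ILC1 markers from 20.2 and 48.1 CPM to 103 and 91.0 CPM, myeloid and dendritic cell markers from 279.5 and 385 CPM to 619 and 611 CPM, and mast cell and basophil markers from 1094 and 1102 CPM to 788 and 708 CPM. Erythroid markers went from 30.5 and 24.7 CPM to 6.18 and 8.66 CPM, B and plasma cell ones from 49.5 and 47.0 CPM to 59.9 and 66.0 CPM, and epithelial, endothelial and stromal ones from 190.0 and 143 CPM to 233 and 261 CPM. In the same comparison the list of co-stimulatory and inhibitory receptors had a median of 0.98, with 5 genes higher over the list alone, and a camera adjusted p of 2.2e-08, or 0.15 with the estimated correlation. The cAMP and CREB target genes had a median of 1.25 with IL-33, again 5 higher over the list alone, and a camera adjusted p of 1.4e-06, or 0.15 with the estimated correlation.

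In vivo, the IL-33 comparison asked how lung ILC2s differ after 3 daily doses. Il13 rose from 28.1 ± 15.4 to 837 ± 149 CPM, a log2 fold change of 4.95 ± 0.34. Il5 rose from 67.0 ± 5.48 to 193 ± 12.5 CPM (1.53 ± 0.22) and Il6 from 1.50 ± 0.403 to 33.2 ± 3.53 CPM (4.49 ± 0.30). Areg stood at 511 ± 121 and 467 ± 0.812 CPM and was not called. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 1.6e-04 for Il13, 0.0015 for Il5, 5.4e-06 for Il6 and 0.80 for Areg, and 4076 genes were higher and 4103 lower among 12187. Of these 8179 genes 8176 moved the same way in both batches. ILC2-like cells held a median of 5057 and 4822 UMIs with PBS, 11039 and 9067 with IL-33, and 7396 and 5923 with IL-33+CGRP. CPM are shares of all UMIs, so rises and falls in vivo, here and below, are relative and need not be changes per cell.

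Cell cycle genes led, 31 of 32 higher and 1 lower, with a median of 3.93 and a camera adjusted p of 3.9e-12, or 0.54 with the estimated correlation. Top2a rose by 4.00 ± 0.57, Mcm3 by 2.87 ± 0.14, Mcm2 by 2.19 ± 0.10 and Pcna by 1.54 ± 0.10. The tumor necrosis factor receptor family gene Tnfrsf8 (CD30) rose by 7.92 ± 0.85, Myb by 6.99 ± 0.66 and the asparagine synthetase gene Asns by 4.51 ± 0.23. MYC and ribosome biogenesis genes rose in 20 of 23 cases with a median of 0.92, among them Srm, a spermidine synthase gene, at 2.06 ± 0.11 and Nop58 at 1.10 ± 0.09. The camera adjusted p was 9.8e-07, or 0.54 with the estimated correlation. Of 21 cholesterol synthesis genes 19 rose, with Idi1 at 2.06 ± 0.14, Cyp51 at 1.81 ± 0.11 and Sqle at 1.69 ± 0.12. Pgam1 rose by 2.09 ± 0.10, Manf by 1.54 ± 0.12, Socs3 by 1.96 ± 0.13, the interferon-induced Bst2 by 1.65 ± 0.22 and Stat1 by 1.03 ± 0.10. Pdcd1 rose by 1.37 ± 0.10, Arg1 by 1.22 ± 0.18 and Klrg1 by 0.68 ± 0.11.

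With IL-33 in vivo Fosb fell by 3.51 ± 0.16, Klf9 by 2.98 ± 0.17, Nr4a1 by 2.41 ± 0.20, Dusp1 by 1.85 ± 0.15 and Tsc22d3 by 1.31 ± 0.12. Of 30 cAMP and CREB target genes 20 fell and 5 rose, with a median of -1.37 and a camera adjusted p of 2.7e-04, or 0.54 with the estimated correlation. That list shares Fos, Fosb, Junb and Ier2 with the fixed list of genes of stress during tissue dissociation. Its changes in vivo, here and below, therefore need not come from cAMP. Ramp3 fell by 1.84 ± 0.23, Calca by 0.88 ± 0.12 and Nmur1, the receptor for another neuropeptide, neuromedin U, by 2.24 ± 0.20. Il7r fell by 1.59 ± 0.10, Icos by 1.45 ± 0.18, Gata3 by 1.08 ± 0.12, Il1rl1 by 0.97 ± 0.10, Cd27 by 2.43 ± 0.11 and Ltb by 1.56 ± 0.09. The clock output genes Nr1d1 and Dbp fell by 3.91 ± 0.27 and 3.62 ± 0.39, Kctd12 by 3.79 ± 0.28 and the lipid enzyme gene Lpcat2 by 3.81 ± 0.21. Tmem176b fell by 1.92 ± 0.11, and summed ILC3 markers went from 2544 and 2372 CPM to 648 and 738 CPM. Epithelial, endothelial and stromal markers fell from 68.5 and 77.5 CPM to 24.0 and 26.3 CPM, and mast cell and basophil ones from 54.4 and 46.0 CPM to 29.6 and 35.2 CPM. Myeloid markers rose from 211 and 209 CPM to 359 and 329 CPM, T cell ones from 181 and 182 CPM to 234 and 235 CPM, B and plasma cell ones from 9.97 and 9.76 CPM to 17.5 and 17.3 CPM, and NK and ILC1 ones from 52.3 and 51.4 CPM to 75.5 and 67.8 CPM.

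CGRP without IL-33 in vivo, the question of its effect on resting lung ILC2s, called 4 of 12187 genes. Hbegf and Prnp (0.73 ± 0.09) rose, while Hspa1b fell by 1.48 ± 0.18 and Map1lc3a by 0.87 ± 0.11, all in both batches. Each had an adjusted p of 0.019 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each call was lost when either PBS sample was left out, with values for the first and the second of 1.39 and 1.21 for Hbegf, 0.75 and 0.71 for Prnp, -1.47 and -1.49 for Hspa1b, and -0.87 for Map1lc3a. Calls were also lost without the first CGRP sample for Hbegf (1.29), Hspa1b (-1.19) and Map1lc3a (-0.87), and without the second for Hbegf (1.31), Prnp (0.61) and Map1lc3a (-0.88). The number of calls ran from 0 (without the first PBS sample) to 5 (without the first CGRP sample). Hspa1b shares much of its sequence with Hspa1a, so its reads are uncertain. Il13 stood at 28.1 and 29.4 CPM, Il5 at 67.0 and 87.5 CPM, Calca at 228 and 233 CPM and Crem at 110 and 63.1 CPM, none of them called. Genes at an unadjusted p below 0.05 numbered 590.0 in edgeR, and DESeq2 called 28 genes after adjustment. Without the batch term edgeR called 0, with 323 genes at an unadjusted p below 0.05.

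CGRP with IL-33 in vivo asked whether the neuropeptide limits the response to IL-33 in the lung. Il13 fell from 837 ± 149 to 90.1 ± 22.3 CPM, a log2 fold change of -3.23 ± 0.30, and Il6 from 33.2 ± 3.53 to 2.72 ± 1.84 CPM (-3.63 ± 0.25). Il5 stood at 193 ± 12.5 and 200 ± 60.8 CPM (0.03 ± 0.21) and Areg at 467 ± 0.812 and 796 ± 285 CPM (0.78 ± 0.40), neither called. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 7.6e-04 for Il13, 1.3e-05 for Il6, 0.93 for Il5 and 0.17 for Areg, and 7187 genes were called, 3548 higher and 3639 lower, of which 7186 moved the same way in both batches.

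Mcm2 fell by 1.52 ± 0.10 and Mcm3 by 1.57 ± 0.13, and 30 of 32 cell cycle genes fell (31 over the list alone), with a median of -1.67 and a camera adjusted p of 8.0e-12, or 0.59 with the estimated correlation. Tnfrsf8 fell by 4.59 ± 0.52, Myb by 4.27 ± 0.43, Asns by 3.25 ± 0.18, Socs3 by 2.24 ± 0.13 and Il2rb by 1.27 ± 0.10. Of 21 cholesterol synthesis genes all 21 fell, with Idi1 at -2.32 ± 0.14, Sqle at -1.72 ± 0.11 and Cyp51 at -1.33 ± 0.10. The camera adjusted p was 1.0e-09, or 0.59 with the estimated correlation. MYC and ribosome biogenesis genes fell in 21 of 23 cases with a median of -1.04, among them Srm at -2.03 ± 0.11 and Nop58 at -1.45 ± 0.09, and the camera adjusted p was 2.2e-09, or 0.59 with the estimated correlation. Pgam1 fell by 1.37 ± 0.09, Manf by 1.34 ± 0.12, Ldha by 0.96 ± 0.09 and Stat1 by 0.67 ± 0.10.

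Calca rose by 1.38 ± 0.12 and Ramp3 by 2.05 ± 0.23, as they had after 6 hours in culture. Csf2, which encodes GM-CSF, rose by 1.32 ± 0.22 from 268 to 665 CPM and Klrg1, an inhibitory receptor of mature ILC2s, by 0.85 ± 0.11 from 150 to 273 CPM. Nr4a1 rose by 1.94 ± 0.20, Zfp36, which destabilises cytokine messages, by 2.63 ± 0.23, Klf9 by 2.71 ± 0.16, Tsc22d3 by 1.62 ± 0.12 and Fosb by 1.77 ± 0.15. Il7r rose by 1.42 ± 0.10, Nmur1 by 1.84 ± 0.20, Cd27 by 1.76 ± 0.11, Icos by 0.96 ± 0.18, Gata3 by 0.81 ± 0.12 and Il1rl1 by 0.50 ± 0.10, while Il17rb fell by 0.84 ± 0.11. Sptssb, a regulator of sphingolipid synthesis, rose by 5.01 ± 0.24, Kctd12 by 3.27 ± 0.28, Dbp by 3.26 ± 0.39, Nr1d1 by 3.23 ± 0.26 and Lpcat2 by 2.90 ± 0.20. Of 30 cAMP and CREB target genes 13 rose and 3 fell, with a median of 0.59 and a camera adjusted p of 0.0055, or 0.59 with the estimated correlation. Summed ILC3 markers went from 648 and 738 CPM to 1610 and 1663 CPM with Tmem176b up by 1.14 ± 0.11, and summed NK and ILC1 markers from 75.5 and 67.8 CPM to 216 and 127 CPM. Those of mast cells and basophils went from 29.6 and 35.2 CPM to 110.5 and 64.6 CPM, and epithelial, endothelial and stromal ones from 24.0 and 26.3 CPM to 48.9 and 86.5 CPM. B and plasma cell markers rose from 17.5 and 17.3 CPM to 37.3 and 22.4 CPM, while myeloid ones fell from 359 and 329 CPM to 299 and 235 CPM.

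**Figure D3:**
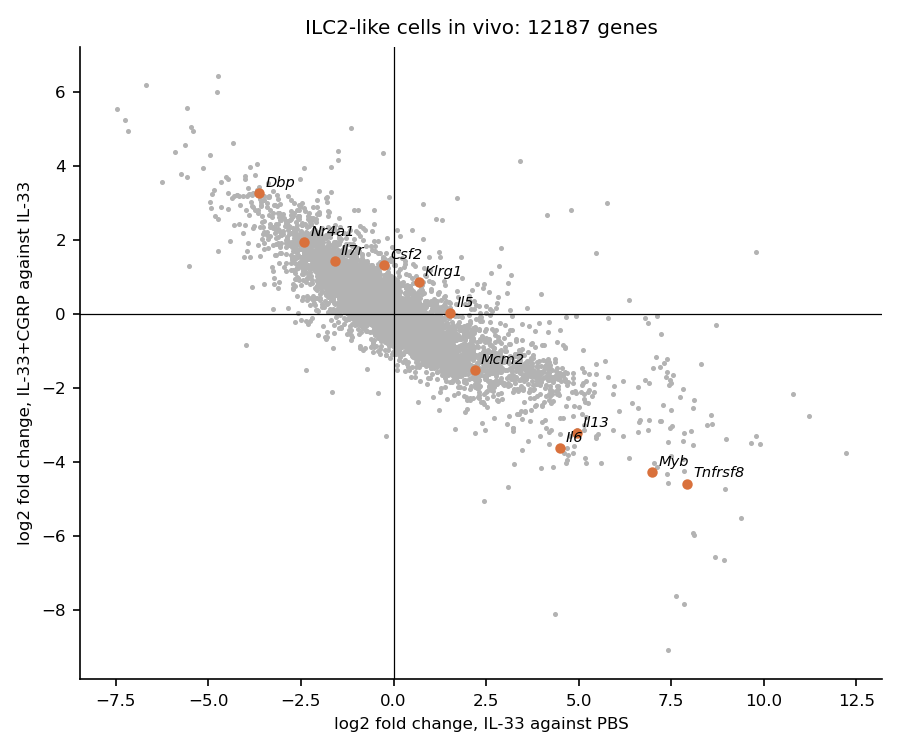
Log2 fold change of 12187 genes in vivo, IL-33 against PBS on the horizontal axis and IL-33+CGRP against IL-33 on the vertical axis; each point is a gene in ILC2-like cells (n = 2 libraries per group) and the labelled genes are named in the text. Il13 lay at 4.95 and -3.23, Nr4a1 at -2.41 and 1.94, and Klrg1 at 0.68 and 0.85.

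The difference between both CGRP effects in vivo, which asks whether CGRP needs IL-33 to act, called 4546 of 12187 genes, 2245 higher and 2301 lower, all in both batches. With 1 library left out the number ran from 2695 (without the second CGRP library) to 4836 (without the first IL-33+CGRP library), and it was 2882 without the first PBS library. Without the batch term 1975 genes were called. Il13 differed by -3.38 ± 0.44, Il6 by -3.93 ± 0.52, Asns by -3.58 ± 0.39, Nr4a1 by 1.99 ± 0.27, Calca by 1.36 ± 0.17, Il7r by 1.22 ± 0.14 and Sptssb by 4.18 ± 0.44. The call of Il13 was lost when the second IL-33+CGRP library was left out, at -3.32. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0047 for Il13 and 0.0011 for Il6. MYC and ribosome biogenesis genes were lower in 20 of 23 cases, with a median of -1.08 and a camera adjusted p of 7.7e-11, or 0.57 with the estimated correlation.

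In single cells, ILC2-like cells made up 60.9 ± 9.81% (SD, n = 2) with PBS, 58.7 ± 2.67% with CGRP, 84.1 ± 1.38% with IL-33 and 72.5 ± 11.7% with IL-33+CGRP. Cluster 2, which scored best for ILC2 markers but stayed out, held 20.8%, 24.0%, 1.00% and 14.2% in the same order. Cluster 10, which also scored best for ILC2 markers and stayed out, went the other way, with 0.879%, 0.470%, 9.59% and 1.11%. The difference in ILC2-like shares between PBS and IL-33 therefore depends in part on the naming rule. Cells of PBS and CGRP libraries lay mostly in clusters 0 and 1, those of IL-33 libraries in clusters 4, 5, 7, 12 and 13, and those of IL-33+CGRP libraries in clusters 3 and 6. The IL-33 libraries differed from each other, with cluster 5 holding 49.9% of ILC2-like cells in the first and 2.71% in the second, and cluster 7 holding 2.05% and 42.3%. The IL-33+CGRP libraries differed too, with cluster 3 holding 28.1% and 67.0%, and cluster 6 holding 42.1% and 11.5%. At 2000 UMIs per cell, 1.87 ± 0.120% of ILC2-like cells had an Il13 UMI with PBS, 2.23 ± 0.089% with CGRP, 45.3 ± 3.68% with IL-33 and 7.51 ± 1.00% with IL-33+CGRP. In the cluster with Klrd1, Nkg7 and Cd3d among its top genes, which should lack Il13, the shares were 0%, 1.05%, 11.5% and 1.15%. Without thinning, Il13 UMIs were found in 77.4% and 68.5% of ILC2-like cells with IL-33 and in 21.8% and 12.7% with IL-33+CGRP, at median depths of 11039 and 9067 UMIs and of 7396 and 5923 UMIs. That other cluster had median depths of 2529 and 2373 UMIs with IL-33 and of 4815 and 4486 UMIs with IL-33+CGRP. Il5 UMIs were in 24.9 ± 0.422% of thinned ILC2-like cells with IL-33 and 22.8 ± 4.12% with IL-33+CGRP, against 7.03% and 4.13% in the other cluster. Klrg1 UMIs were in 25.3 ± 1.58% and 36.9 ± 5.23%, against 7.63% and 6.02%.

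**Figure D4:**
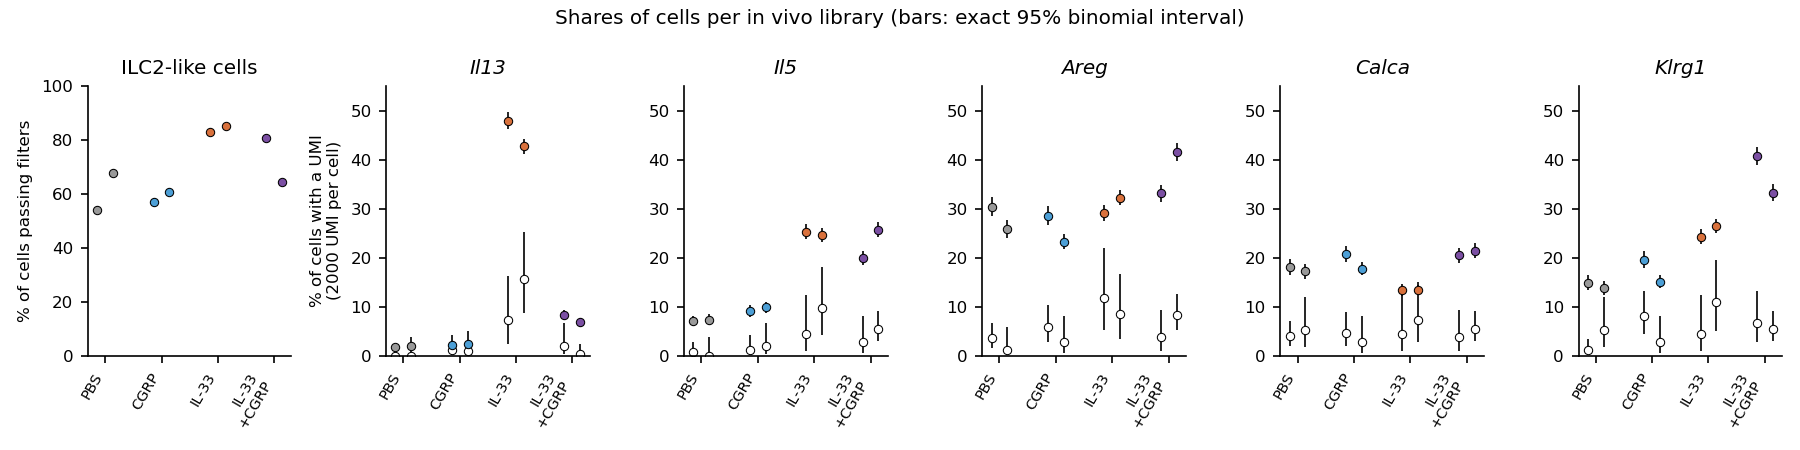
Share of ILC2-like cells per library in percent of all cells, and share of cells with a UMI of Il13, Il5, Areg, Calca or Klrg1 at 2000 UMIs per cell, on the vertical axes by treatment; filled points are ILC2-like cells and open points the cluster with Klrd1, Nkg7 and Cd3d among its top genes, 1 point per library with exact 95% binomial intervals. Il13 was found in 45.3% of ILC2-like cells with IL-33 and in 7.51% with IL-33+CGRP.

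Chromatin accessibility at 6 hours with IL-33 asked where CGRP changes regulatory DNA. Of 90448 tested regions 12869 were called at an adjusted p below 0.05 by limma on log2 signal with Benjamini-Hochberg adjustment, 8189 more open and 4680 less open with CGRP. With 1 library left out 8310 (without the second IL-7+IL-33+CGRP library, 8495 without the first) to 12512 regions (without the third IL-7+IL-33 library) were called. Over all 90448 tested regions the groups did not overlap in 30.3%, where 10.0% are due by chance. At Il13 7 of 10 regions closed. The region at chr11:53628419-53629784, 1539 bp from the gene, went from a signal of 163 ± 65.9 to 18.4 ± 6.46 (SD, n = 3), a log2 fold change of -3.10 ± 0.28, and the region at chr11:53629854-53631329 within the gene from 568 ± 160 to 149 ± 12.1 (-1.89 ± 0.15). At Il5, on the same chromosome, 2 of 15 regions opened and 1 closed, led by chr11:53714697-53715198 at 2.04 ± 0.41 and chr11:53720543-53721116 in the gene at 0.89 ± 0.15.

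At Crem 10 of 21 regions opened, led by chr18:3260619-3262825 at 3.58 ± 0.31, from a signal of 12.0 ± 6.44 to 133 ± 27.9. At Il1rl1 12 of 41 regions opened, with chr1:40425321-40425822 at 2.85 ± 0.35 and chr1:40448244-40448747 at 1.94 ± 0.20, both within the gene. At Calca 5 of 7 regions opened, chr7:114616679-114617188 with the lowest adjusted p by 0.41 ± 0.09, chr7:114646076-114646610 by 1.16 ± 0.32 and chr7:114671334-114671853 by 0.92 ± 0.25, beside a change of Calca messages of 5.77. The calls of the last 2 were lost without the first IL-7+IL-33 library (0.78 and 0.78) and without the second IL-7+IL-33+CGRP library (1.10 and 0.84). At Klrg1 2 regions opened and 2 closed of 19, with chr6:122293785-122295686 at -0.96 ± 0.11. The largest openings included regions near Igf1r, chr7:67878369-67878870 at 3.99 ± 0.37, near Lmo4, chr3:144187090-144187591 at 3.68 ± 0.46, and near the oxygen sensor gene Egln3, chr12:54176518-54177019 at 3.79 ± 0.77. The largest closings included chr4:12785004-12785505 at -3.89 ± 0.84, with no gene within 100 kb, and chr13:21337118-21337619 near Olfr1367 at -3.85 ± 0.64. Signals near 0 carry 1 added read, so log2 changes of weak regions are understated.

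**Figure D5:**
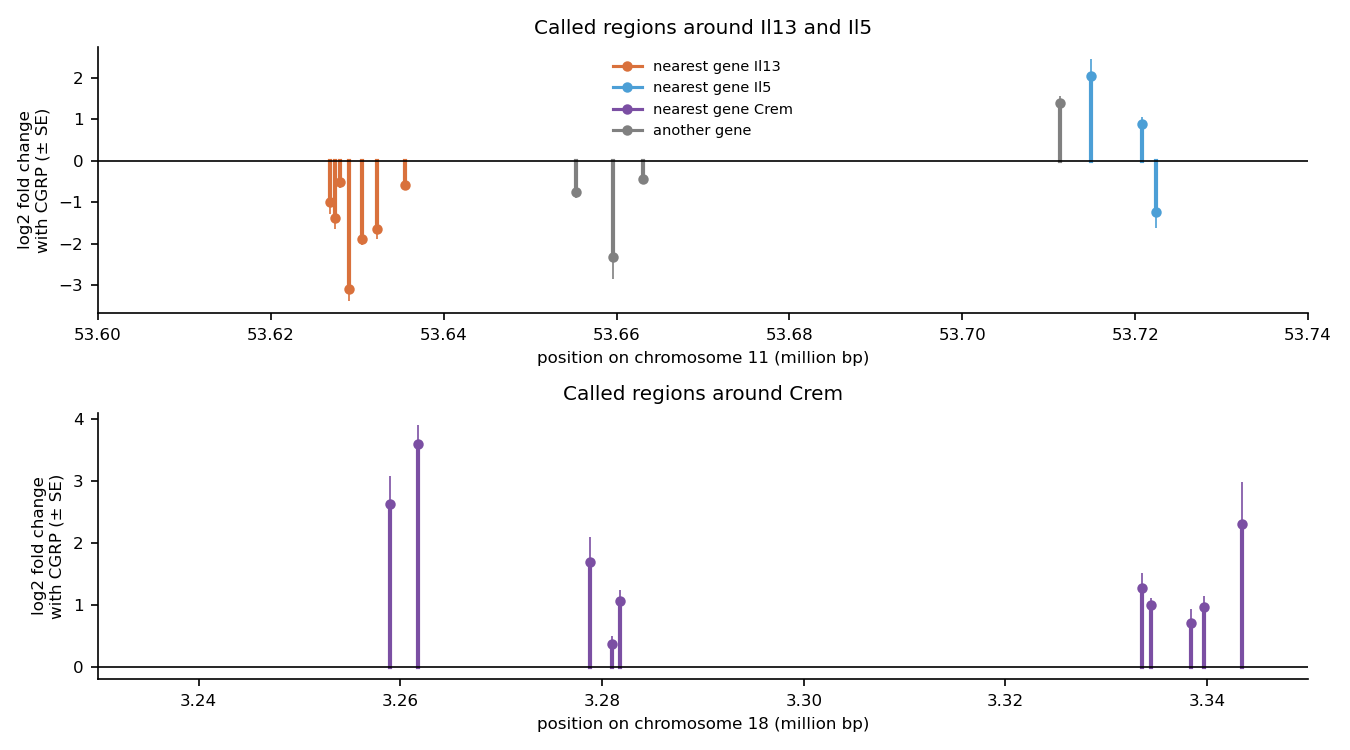
Log2 fold change of called regions with IL-7+IL-33+CGRP against IL-7+IL-33 (n = 3 libraries per group) on the vertical axis by position in Mb on the horizontal axis, around Il13 and Il5 on chromosome 11 and around Crem on chromosome 18; bars are standard errors and colours the nearest gene. The 7 called regions of Il13 lie below 0, down to -3.10, and the 10 of Crem lie above 0, up to 3.58.

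Opened regions and raised genes went together. An opened region lay nearest to 563 of 972 raised genes (57.9%) and to 23.0% of other genes, an odds ratio of 4.60 (95% interval 4.01 to 5.27, Fisher's exact p = 2.9e-109). A closed region lay nearest to 344 of 1115 lowered genes (30.9%) and to 17.3% of the others, an odds ratio of 2.13 (1.85 to 2.45, Fisher's exact p = 1.3e-25). Raised genes had a median of 7 regions and others 3, and given the number of regions the odds ratios were 3.12 for opened regions and raised genes and 2.73 for closed regions and lowered genes. Closed regions lay near raised genes with an odds ratio of 0.99, or 0.40 given the number of regions. Genes are not independent replicates, so these p-values describe this set of samples.

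Across experiments, CGRP with IL-33 raised 445 genes both at 6 hours and in vivo, where 275 were due by chance, and lowered 756 in both, where 347 were due, while 312 moved in opposite directions. Of the 1090 genes that IL-33 raised at 6 hours and that were measured in vivo, 790.0 were lower and 93 higher with CGRP in vivo, with a camera adjusted p of 1.5e-22, or 0.085 with the estimated correlation. The response to IL-33 itself shared 780.0 raised genes between 6 hours and in vivo, where 382 were due by chance, and 408 lowered genes, where 218 were due, while 234 moved in opposite directions. Between 6 hours and 3 days it shared 291 raised genes, where 36.3 were due, and 151 lowered genes, where 15.1 were due, with 9 in opposite directions.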

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

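The interaction tests behind the 6 results of this part were set before their results were seen, while the genes named for the time differences were chosen afterwards from the fixed genes. Each of the 6 is a difference between groups, since the same treatment changed a gene by different amounts in 2 settings. In the 8 culture groups no library stood far from the other 3 in total counts or in genes detected, the highest share of the range that a gap took being 0.767, under the 95% limit of Dixon's test that chance exceeds in about 1 of 20 groups. The in vivo and ATAC groups were too small for that test, and the 4 culture libraries of a group are 2 pairs.

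The response to CGRP differed with and without IL-33 for 66 of 13279 genes after 6 hours of culture and for 4546 of 12187 genes in vivo, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 66 and all 4546 moved the same way in both batches, which is no separate evidence because the same samples made the calls. With 1 sample left out the first number ran from 1 (without the second IL-7+IL-33+CGRP sample) to 13 (without the second IL-7 sample), with 10 without the first IL-7 sample, 4 without either IL-7+CGRP sample, 3 without either IL-7+IL-33 sample and 5 without the first IL-7+IL-33+CGRP sample. The second number fell to 2695 without the second CGRP library and to 2882 without the first PBS library.

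Between 6 hours and 3 days, with both times in 1 fit over 13960 genes, the IL-33 effect differed for 145 genes, 63 higher and 82 lower at 3 days. The CGRP effect differed for 84 genes without IL-33 (16 higher, 68 lower) and for 184 genes with IL-33 (109 higher, 75 lower). The difference between both CGRP effects itself differed for 14 genes, 12 higher and 2 lower. The labels do not say whether both times came from the same cultures, so these tests do not separate the duration of exposure from a difference between cultures.

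Among the fixed genes, the CGRP effect with IL-33 was smaller at 3 days for Calca (-4.34), Crem (-2.41) and Ramp3 (-3.20), and that on Il5 was lower by 1.82, with an estimate of 1.23 at 6 hours and of -0.57, which was not called, at 3 days. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0042 for Calca, 0.0041 for Crem, 0.029 for Ramp3 and 0.011 for Il5. Without IL-33 it was smaller for Calca (-3.18) and Il5 (-1.99), with an adjusted p of 0.027 and 0.012 by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and not called for Crem (-0.98) or Ramp3 (0.38). The effect of IL-33 on Il7r was lower at 3 days (-1.47) and that on Ramp3 higher (3.30), with an adjusted p of 0.0018 and 0.034 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Il13 did not pass it for the CGRP effect with IL-33 (2.26).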

How the results depend on the processing

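The alternatives added after the data had been seen were the 10.0 CPM filter, the sums with 3 unnamed clusters, the sums without the 5% of cells with the most UMIs, the thinned counts, and edgeR and TMM-scaled limma on recovered ATAC reads; all others had been set before. Genes whose call held with any sample left out had been preferred for the text after the results were seen. The numbers for named genes in this paragraph may therefore overstate how well called genes in general held. Named genes kept their direction under every alternative run, in 2039 values at 6 hours, 533 at 3 days and 2026 in vivo, and named regions in 587. They also kept their side of the threshold in 1827, 347, 1891 and 542 of these. Of the 212, 186, 135 and 45 calls that ended, 130, 162, 51 and 23 ended with a left-out sample, where the lone sample of a group is assumed to vary like those of the other groups.

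DESeq2 called 2852, 2171, 3245 and 668 genes at 6 hours for IL-33, for CGRP without and with IL-33 and for the difference between both CGRP effects, against 1806, 1152, 2118 and 66 in edgeR. At 3 days it called 2212, 994, 330 and 260 against 690.0, 0, 0 and 0, and in vivo 28 against 4 for CGRP without IL-33; the cause was not tested. With both times in 1 fit, which estimates the spread from more samples, the numbers were 830.0, 524, 1085 and 18 at 6 hours and 1891, 503, 181 and 37 at 3 days. With each library as its own sample, which doubles the number of samples, they were 1784 for CGRP without IL-33 and 327 for the difference at 6 hours, and 1468, 299, 141 and 54 at 3 days. The first library of each batch alone gave 937, 682, 1142 and 14 at 6 hours and 166 for IL-33 at 3 days, where the counts were fewer.

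Where a call also required an estimated absolute log2 fold change of at least 1, which can only end calls, there were 881, 621 and 1093 genes at 6 hours for IL-33 and for CGRP without and with it, and 3478, 2, 2294 and 1659 in vivo, with 6331 regions. With a 10.0 CPM filter 1742 genes were called for CGRP without IL-33 and 331 for the difference at 6 hours, and 35, 22 and 1 for CGRP without and with IL-33 and for the difference at 3 days. At 3 days CGRP without IL-33 called 1 gene with RLE factors and 1 without a low-count filter. Without the replicate block of batches it called 22 genes and CGRP with IL-33 called 9, while in vivo the difference called 1975 genes and CGRP without IL-33 called 0; the cause was not tested. CGRP without IL-33 in vivo called 36 genes without a low-count filter, 0 over all cells, 0 without a filter on cells, 1 with 3 unnamed clusters and 2 from thinned sums; the cause was not tested. Where edgeR called 0 in vivo, 323 genes without the block, 516 over all cells and 521 without a filter on cells had an unadjusted p below 0.05.

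With 1 sample left out, the number of called genes at 6 hours ran from 505 (without the second IL-7+IL-33 sample) to 871 (without the first IL-7 sample) for IL-33 and from 428 (without the second IL-7+CGRP sample) to 765 (without the first) for CGRP without IL-33. It ran from 661 (without the second IL-7+IL-33 sample) to 1237 (without the first IL-7+IL-33+CGRP sample) for CGRP with IL-33 and from 1 (without the second IL-7+IL-33+CGRP sample) to 13 (without the second IL-7 sample) for the difference. At 3 days it ran from 0 (without the first IL-7 sample or either IL-7+IL-33 sample) to 6 (without the second IL-7 sample) for IL-33, with 1311 to 2375 genes at an unadjusted p below 0.05 in edgeR where 0 were called. For CGRP without IL-33 and for the difference it ran from 0 to 1312 and to 557, both without the first IL-7+CGRP sample. In vivo it ran from 0 (without either PBS library) to 5 (without the first CGRP library) for CGRP without IL-33 and from 2695 (without the second CGRP library) to 4836 (without the first IL-33+CGRP library) for the difference. Regions ran from 8310 (without the second IL-7+IL-33+CGRP library) to 12512 (without the third IL-7+IL-33 library).

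For regions the other alternatives lay between 9662 (DESeq2) and 13472 (edgeR on recovered reads) around 12869, with 11253 in thinned libraries. A replicate block on the replicate numbers called 16064, but the numbers were not taken to pair the libraries, because the labels name no shared batch or day and deviations of libraries of 1 number correlated at 0.046, 0.035 and 0.128. That 5 of 6 libraries lay closest to one of their own number is a hint of pairing from the data. The odds ratio of closed regions and raised genes, 0.99, lay on the other side of 1 with regions called by edgeR (1.01) and ran from 0.84 to 1.02 with 1 library left out; the cause was not tested. Given the number of regions it was 0.40, and 0.32 to 0.41 in the alternatives. For opened regions and raised genes it stayed between 4.54 and 5.02.

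Of 300 tests of gene lists 90.0 were called with the preset correlation and 0 by camera with the estimated one and the lowest adjusted p was then 0.057. Other alternatives called 30.0 to 36 lists at 6 hours, 23 to 39 at 3 days and 29 to 42 in vivo. A called list changed direction in 2 of these 47 alternatives, 1 at 3 days and 1 in vivo. Of 24 tested transfers of gene sets 22 were called, and 14 with the estimated correlation; 20 of the 24 were between experiments, with 20 and 12 called, and 4 between both CGRP effects of 1 experiment, with 2 and 2 called. The share of ILC2-like cells with IL-33 was 80.8% without a mitochondrial filter, against 84.1%.

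In simulated CGRP with IL-33, 22.2% of 4-fold changes were recovered at 3 days and 90.7% at 6 hours, at sums of 28.7 to 36.7 M and 28.3 to 39.9 M counts. These similar sums argue against depth as the cause of the lower recovery at 3 days, though no test separated depth from spread. Thinning to the smallest library lowered the number of called regions from 12869 to 11253. Leaving out Scrublet doublets changed no call number. Distances to a transcription start were replaced by distances to the gene span.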

Other observations

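The predictions for the 6 tests of this part had been written before their results were seen, while the patterns were noticed in the data. The only biological explanation tested was a higher share of cells in the cell cycle, and that test decided nothing.

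The number of accessible regions that differed with CGRP, 12869, was weighed against depth, because libraries with CGRP had 8.92 to 10.77 M reads in regions and those without 6.78 to 7.22 M. With every library thinned to the smallest total limma with Benjamini-Hochberg adjustment called 11253 regions, which argues against depth as the whole cause. Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many regions, the real one at 12869, and the highest other called 0, but 10 splits are too few for a share under 0.05. Groups did not overlap in 30.3% of 90448 tested regions, where 10.0% are due by chance.

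The clock output genes Dbp and Nr1d1 were lower with IL-33 in vivo (-3.62 ± 0.39 and -3.91 ± 0.27) and higher with IL-33+CGRP than with IL-33 (3.26 ± 0.39 and 3.23 ± 0.26). A different time of day of tissue collection may have moved them, but it would raise Arntl and Npas2, which run in antiphase. These were lower as well, at -0.81 ± 0.11 and -1.54 ± 0.31, with a mean of -1.18, against that prediction. CPM are relative, however, and ILC2-like cells held a median of 5057 and 4822 UMIs with PBS and 11039 and 9067 with IL-33. A lower share of UMIs need not be a fall per cell, and Npas2 stood at only 3.36 and 1.15 CPM. The sign of these changes therefore cannot decide on a shift in time. Nfil3 and Cry1 did move as such a shift would have it, up with IL-33 (0.92 ± 0.10 and 1.55 ± 0.15) and down with IL-33+CGRP against IL-33 (-0.76 ± 0.10 and -0.58 ± 0.13), so a part in it stays open. A higher share of cells in the cell cycle with IL-33 remains open. In ILC2-like cells with no UMI of the cell cycle list the mean of Dbp and Nr1d1 was -2.32, against -3.77 in all ILC2-like cells, with -1.93 ± 0.60 for Dbp and -2.70 ± 0.42 for Nr1d1. These cells were only 3.22% to 11.41% of the ILC2-like cells of a library, and a lack of such UMIs also follows from low depth, so the test decides nothing.

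Across 12187 genes in vivo the IL-33 effect and the CGRP effect with IL-33 ran in opposite directions. Both effects share the IL-33 libraries, which alone gave correlations of -0.396 and -0.425 in simulated counts without any effect. With the IL-33 effect from 1 batch and the CGRP effect from the other, which share no library, the correlations were -0.722 and -0.860, against -0.008 in simulated counts. With every sum thinned to the smallest total they were -0.628 and -0.774, which argues against depth. Il5 and Klrg1 did not follow this, with IL-33 effects of 1.53 and 0.68 and CGRP effects of 0.03 and 0.85.

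Cluster 10, which stayed without a name, held 9.59% of cells with IL-33 and 0.879%, 0.470% and 1.11% with PBS, CGRP and IL-33+CGRP. UMIs of the MHC class II genes H2-Aa, H2-Ab1 and Cd74 were in 82.88%, 85.10% and 92.75% of its cells, against 6.25%, 12.65% and 23.43% in cluster 5 and 6.69%, 10.65% and 26.08% in cluster 7.

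Libraries that shared a batch letter differed by more than counting allows. The standard deviation of their log2 difference across genes was 0.952 to 1.571 at 6 hours, and 0.618 (the first batch of IL-7+IL-33) to 3.405 (the second batch of IL-7+CGRP) at 3 days. Between single libraries of different batches of a group it averaged 1.15 to 1.383 at 6 hours. In each group at 6 hours that value lay above the one within the first batch and below the one within the second. The series design text describes a split of each biological replicate into 2 technical replicates, and n = 2 rests on that description.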
